A study of Mus musculus with 6 samples.

How the data were processed

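The study profiled iNKT cells of PLZF_ON and WT mice, 3 arrays per group, on Affymetrix whole-transcript arrays with biotin-labelled targets made from total RNA, per the labels' protocols. The labels give the cell type as iNKT cells while the extraction protocol speaks of frozen tissue; the organ and the way the cells were isolated are not given in the sources used here. The deposited table holds log2 expression values, 1 row per array feature, and RMA is named in the submitters' processing notes, without a version. RMA subtracts background, brings all arrays to a common distribution and summarises the probes of a row on the log2 scale; it compresses changes of dim genes. The genome build and the array annotation used by the authors are not given in the sources used here. The deposited log2 values were used as they stand, with no further background correction or scaling.

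Of 41345 deposited rows, 25335 were named through the platform annotation. Exactly 1 gene symbol was given for 23521 rows, which were tested, several symbols for 1814 rows, which were left out, and 16010 rows were not listed in the table and stay unnamed here. By Entrez number 23328 of the tested rows matched the NCBI gene table of assembly GRCm38.p6, and 0 symbols had to be updated; that table was used for names and gene order only. The tested rows stood for 22180 genes, of which 1082 had several rows, and a gene was represented by its row with the highest mean over the 6 arrays. No row was left out for low intensity.

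Groups were taken from the genotype labels. The comparison over 4 arrays used WT and PLZF_ON replicates 1 and 2, which the design description names as the arrays analysed, and a second comparison used all 6 arrays. Each was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, two-sided), with genotype as the only term, and adjusted by Benjamini-Hochberg over the tested rows at 0.05. Standard errors are the moderated ones of limma. The 4-array fit had 2 residual degrees of freedom and 4.10 from the prior, and the 6-array fit 4 and 3.78. The replicate 3 arrays were also compared with each other as differences, without a test.

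The 26 gene lists hold 487 different genes, of which 432 were measured, and were written before the data were examined, as were the comparisons, the rule for named genes and the alternatives. Lists were tested by the count of members passing limma over all rows and adjusted over the list alone, by camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry, each adjusted over the lists. Named genes were the 10 largest rises and 10 largest falls among rows passing the 4-array test whose groups did not overlap and whose higher group mean was at least the median of all rows, 5 and 5 by the same rule over 6 arrays, and up to 4 members per list with the smallest p. Predicted genes and microRNA, small nucleolar RNA, olfactory and vomeronasal receptor genes were counted but not named, and Zbtb16 was always given. Other genes in the text (among them Ifng, Prf1, Cd24a, Dntt, Rag2, Top2a, Kif11, Siae and those named with small counts) were chosen after their values were seen. The deposited values carry no detection flag, so the 95th percentile of the means of 1394 olfactory and vomeronasal receptor genes was set beside the named genes, a limit also chosen after the results were seen.

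Scripts were tested on simulated data with the real WT means of all 23521 rows. The spread of each row was drawn at random from the variance prior fitted by limma, with normal noise. The simulated data thus follow the assumptions of the test, and the real data may be recovered less well. With 2 arrays per group 82% of changes of 1.5 and 99% of changes of 3 on the log2 scale were recovered, with 4 false calls, and with 3 arrays per group 81% and 99%, with 12 false calls. No list was called in either simulation without an effect. The simulated rows were independent of each other, while the estimated correlation over 4 arrays was 0.75 for NKT1-associated and 0.93 for cell cycle genes. The simulation therefore does not show how often camera at the preset correlation calls a list of correlated genes by chance. Alternatives were the replicate number as a block, leaving out each array, brighter rows alone, a variance trend, quantile normalization again, median centring, all deposited rows, array weights, other thresholds, and the mean of a gene's rows. Figures were drawn with matplotlib 3.10.9.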

Results

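Gene expression was measured on whole-transcript microarrays in invariant natural killer T (iNKT) cells of mice. These T cells carry a nearly fixed T cell receptor, recognise lipids presented by CD1d, and depend on the transcription factor PLZF, encoded by Zbtb16. The 6 arrays fell into 2 groups of 3, wild type (WT) and PLZF_ON, the latter from mice that express a PLZF protein kept in its acetylated form. Of these, 4 arrays (replicates 1 and 2 of each group) were named by the study as those used in its analyses, and replicate 3 of each group was deposited beside them. The arrays had median log2 values between 4.88 and 5.01. Correlations between arrays ranged from 0.957 to 0.973 across rows, apart from those of PLZF_ON replicate 3 with the other 5 arrays, which lay between 0.895 and 0.898. The spread over rows was also narrower in that array, with an SD of 1.79 against 1.97 to 2.01 in the others. The number of arrays limits the precision of all values. Nothing in the labels says whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

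Zbtb16 itself was measured on all 6 arrays. Its log2 level was 9.96, 10.19 and 9.82 in WT replicates 1 to 3 and 10.48, 10.68 and 9.54 in PLZF_ON replicates 1 to 3. Over the 4 arrays the difference was 0.51 on the log2 scale (SE 0.15, limma adjusted p = 0.369), and over all 6 it was 0.24 (SE 0.30, limma adjusted p = 0.941). An altered acetylation of the protein need not alter its mRNA, so these levels do not check the labels.

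The comparison of PLZF_ON with WT over the 4 arrays asked which transcripts of iNKT cells differ when PLZF is constitutively acetylated. Itgae, the CD103 integrin chain that binds E-cadherin, showed the largest fall among genes passing the test, by 3.69 on the log2 scale, or 12.9-fold (SE 0.17, n = 2 arrays per group, limma adjusted p = 0.00693). Il1r1 and Il23r, receptors for interleukin-1 and interleukin-23, fell 10.4-fold and 8.85-fold, and Blk, a Src family kinase, fell 6.53-fold. Akr1c18, a hydroxysteroid dehydrogenase, rose 22.2-fold, by 4.47 on the log2 scale (SE 0.31, n = 2 arrays per group, limma adjusted p = 0.0173). The lower group of Il1r1, Il23r, Blk and Akr1c18 was not shown to be above background, with means of 4.56, 3.83, 4.72 and 4.23, below the 95th percentile of olfactory and vomeronasal receptor genes (5.08), which iNKT cells are not expected to express. Taken against that percentile their folds were 7.32, 3.73, 5.11 and 12.3. Transcripts associated with NKT1 cells and with NK receptors were mostly lower in PLZF_ON, and most of those associated with NKT2 cells were higher. Without PLZF_ON replicate 2 none of the 5 named genes passed (limma adjusted p from 0.0874 for Itgae and Il1r1 to 0.19 for Blk), and without PLZF_ON replicate 1 Akr1c18 (0.0656), Il23r and Blk (0.0825 each) did not.

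The other large rises among genes passing the test were in Moxd1 (18.4-fold), Vsig2 (13.4-fold), Nrgn, the calmodulin-binding protein neurogranin (7.85-fold), and Irak3, an inhibitor of Toll-like receptor signalling (7.35-fold). Tnfsf8, the CD30 ligand, rose 6.27-fold, Exph5 6.26-fold, the peptide transporter Slc15a1 5.59-fold, the sodium-potassium-chloride cotransporter Slc12a2 5.37-fold and Spa17 4.65-fold. Standard errors of these 9 log2 changes ran from 0.17 to 0.28, and their limma adjusted p-values from 0.00693 to 0.0456. Among the falls, Trgv5, a T cell receptor gamma variable segment, fell 4.92-fold, Pcsk1, a prohormone convertase, 3.59-fold, Prag1 3.53-fold and Fgl2 3.42-fold. Cdh1, which encodes E-cadherin, fell 4.22-fold, and both of its rows passed the test. Haspin, a histone H3 kinase, fell by 2.29 on the log2 scale. Standard errors of the log2 changes of the 9 named genes that fell beside Itgae ran from 0.13 to 0.26, and their limma adjusted p-values from 0.00953 to 0.0279. For Moxd1, Vsig2, Irak3, Tnfsf8, Exph5, Slc15a1, Trgv5 and Pcsk1 the lower group also lay below that percentile, making 12 of the 20 named genes, and the folds of these 8 against it were all smaller, with 2.10 for Pcsk1 and 9.68 for Moxd1. Haspin lies inside Itgae in the gene table, so a signal from Itgae transcripts in its value was not excluded. Spa17 overlaps Siae, whose log2 difference was 1.51 (SE 0.23, limma adjusted p = 0.0982). Without PLZF_ON replicate 2 all 20 named genes lost the call (adjusted p from 0.0874 to 0.25), and without PLZF_ON replicate 1 11 of them did (0.0523 to 0.115), which were Akr1c18, Nrgn, Tnfsf8, Exph5, Slc12a2, Il23r, Blk, Cdh1, Pcsk1, Prag1 and Fgl2.

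In all, 40 of 23521 tested rows passed a limma adjusted p of 0.05, 24 higher and 16 lower, and stood for 39 genes. An unadjusted p under 0.05 was reached by 2213 rows, against 1176 expected by chance, and 972 of these had a fold of at least 1.5 (533 higher and 439 lower). Without PLZF_ON replicate 2 the limma count was 0, with 1803 rows under an unadjusted p of 0.05, and without WT replicate 2 it was 106. Without PLZF_ON replicate 1 it was 32, with 9 higher and 23 lower, so the majority of rises was not kept. When all 41345 deposited rows were tested together, none passed with limma (smallest adjusted p = 0.252), and 3042 rows had an unadjusted p under 0.05.

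**Figure D1:**
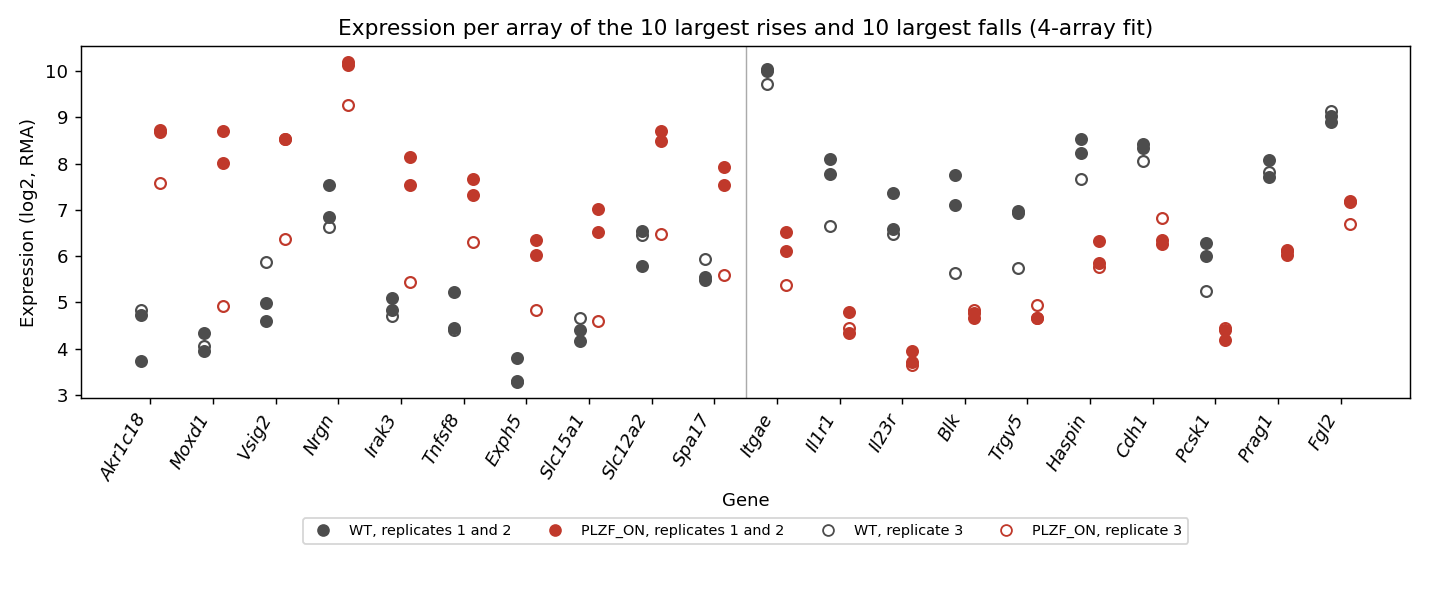
Expression in log2 units (vertical axis) of the genes named from the 4 arrays (horizontal axis), 1 point per array. They are the 10 largest rises and 10 largest falls among genes that passed limma and met the rule for named genes. Filled points are the 4 arrays of the comparison and open points are replicate 3 of each group; Itgae lay between 9.73 and 10.04 in WT and between 5.39 and 6.53 in PLZF_ON.

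Each gene list was tested with limma, gene by gene, and with camera, which compares the changes of a list with those of all other genes. Of the 26 lists, 14 passed camera at a preset correlation between genes (6 higher and 8 lower), and 0 passed with an estimated correlation, where the smallest adjusted p was 0.394 and 2 lists had an unadjusted p under 0.05. By fry, which tests whether the genes of a list move on balance in a single direction, 0 lists passed over the 4 arrays (smallest adjusted p = 0.118), and 6 had an unadjusted p under 0.05.

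NKT1-associated transcripts, those of the interferon-gamma-producing subset, were lower in PLZF_ON for 24 of 26 measured members, with a median log2 difference of -1.45 (camera adjusted p = 4.3e-17, and adjusted p = 0.445 with an estimated correlation). In limma 15 members fell and 0 rose adjusted over the list alone, while 0 passed over all rows and 18 had an unadjusted p under 0.05. Gzmb, a cytotoxic protease, fell 13.9-fold over the list alone, Tbx21, the T-bet transcription factor of the subset, 2.88-fold, Il12rb2 4.15-fold and Nkg7 3.36-fold. Ifng itself was at 6.90 in WT and 5.74 in PLZF_ON and did not pass. NK receptors, most of them C-type lectins shared with natural killer cells, were lower for 18 of 19 members (median -1.13, camera adjusted p = 6.8e-12, and adjusted p = 0.445 with an estimated correlation), and 3 of them are also in the NKT1-associated list. In this list 11 fell and 0 rose adjusted over the list alone, among them Klra5 (10.4-fold) and Klrb1c, which encodes NK1.1 (4.56-fold). Cd226 fell 3.02-fold, and was the only NK receptor to pass over all rows. PLZF_ON replicate 2 set much of the size of both falls. The NKT1-associated median was 9.26 and 9.04 in WT, 8.32 in PLZF_ON replicate 1 and 6.72 in replicate 2, and that of NK receptors 7.71, 7.49, 7.28 and 4.92. Without PLZF_ON replicate 2 the median differences were -0.69 (21 of 26 lower) and -0.56 (15 of 19 lower), and without PLZF_ON replicate 1 they were -2.06 and -1.70.

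Cytotoxic granule transcripts, 5 of which are in the NKT1-associated list, had a median of -0.52 (17 measured, camera adjusted p = 2.1e-05, and adjusted p = 0.445 with an estimated correlation). Adjusted over the list alone, 8 fell, including Fasl (7.64-fold) and Ctsd (1.88-fold), and 1 rose, the lysosomal membrane protein Lamp1, while 0 passed over all rows. Perforin (Prf1) had a log2 difference of -0.35 and did not pass. In PLZF_ON replicates 1 and 2 Fasl was at 6.52 and 4.97, against a WT mean of 8.68, and Prf1 at 6.87 and 6.14, against 6.85. Without PLZF_ON replicate 2 the median of the list was -0.28, with 9 of 17 lower.

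Tissue residency transcripts were lower for 13 of 14 members (median -0.83, camera adjusted p = 6.8e-12, and adjusted p = 0.445 with an estimated correlation). Of the residency transcripts 9 fell and 0 rose adjusted over the list alone, and 1, Itgae, also passed over all rows. Itga1, the alpha chain of the collagen receptor CD49a, fell 3.94-fold over the list alone, Rgs1 3.01-fold and Bhlhe40 2.55-fold. Egress and naive T cell transcripts were mostly higher (13 measured, median 0.44, camera adjusted p = 9.6e-06, and adjusted p = 0.394 with an estimated correlation). Of these, 6 rose and 0 fell adjusted over the list alone, and 1, the transcription factor Lef1, rose 3.08-fold and also passed over all rows. The sphingosine-1-phosphate receptor S1pr1 rose 2.37-fold over the list alone, Ccr7 2.38-fold and Nsg2 2.29-fold.

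NKT2-associated transcripts, those of the interleukin-4-producing subset, were higher for 13 of 15 members (median 0.65, camera adjusted p = 2.5e-10, and adjusted p = 0.394 with an estimated correlation). Adjusted over the list alone, 10 rose and 1, Il4ra, fell, and 0 passed over all rows. Irf4 rose 2.63-fold over the list alone, Il6ra 2.33-fold, Egr2 1.96-fold and the cytokine Il13 2.09-fold. Il4 itself had a log2 difference of 0.45 and did not pass. Other lists hold 9 of the 15 members too, these 4 that rose among them. NKT17-associated transcripts had a median of -0.46 (22 measured, camera adjusted p = 1.4e-08, and adjusted p = 0.394 with an estimated correlation). Of these, 13 fell and 2 rose adjusted over the list alone, and 3 passed over all rows, namely Il1r1, Blk and Il23r. Sdc1, a surface proteoglycan used as a marker of the subset, fell 3.33-fold over the list alone, although its other row had a log2 difference of -0.22. The members that rose were Emb and Cd163l1, although the other row of Emb had a log2 difference of 0.11.

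Immature thymocyte transcripts had a median of 0.34 (14 measured, camera adjusted p = 2.6e-05, and adjusted p = 0.394 with an estimated correlation). Adjusted over the list alone, 5 rose and 0 fell, and 1, the T cell signalling protein Themis, rose 3.88-fold and also passed over all rows. Ccr9, a homing receptor, rose 2.27-fold over the list alone, Ets2 1.89-fold and Myb 1.69-fold. The markers of the most immature cells did not pass, with log2 differences of -0.19 for Cd24a, 0.20 for Dntt and 0.10 for Rag2.

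Cytokine receptors were divided, with 9 falls and 3 rises adjusted over the list alone and 2, Il1r1 and Il23r, passing over all rows (24 measured, median -0.28, camera adjusted p = 4.0e-04, and adjusted p = 0.445 with an estimated correlation). Il12rb2 fell and Il6ra rose over the list alone, as given above. NF-kB targets had a median of -0.13 (23 measured, camera adjusted p = 0.00237, and adjusted p = 0.445 with an estimated correlation). Adjusted over the list alone, 4 fell (Nfkbie, Traf1, Nfkb2 and Tnfaip3, from 1.62-fold to 1.91-fold) and 0 rose, while 0 passed over all rows. Without PLZF_ON replicate 2 the camera adjusted p of this list was 0.129 and its median -0.03, and without WT replicate 2 the median was -0.21.

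Cell cycle transcripts were higher for 33 of 34 members, with a median of 0.58 (camera adjusted p = 4.9e-08, and adjusted p = 0.59 with an estimated correlation). By limma 0 passed adjusted over the list alone or over all rows, and 5 had an unadjusted p under 0.05. Kif11, a mitotic kinesin, had a log2 difference of 1.44, Top2a 1.24, Tyms 1.06 and Aurka 0.68. The median of the list was 5.99 and 7.08 in WT replicates 1 and 2 and 6.65 and 7.65 in PLZF_ON replicates 1 and 2, so that WT replicate 2 lay above PLZF_ON replicate 1, while PLZF_ON lay above WT within each replicate number. With the replicate number as a block, which the labels do not give as a pairing, 19 rose adjusted over the list alone and 1 passed over all rows. Without WT replicate 1 the camera adjusted p was 0.211 and the median 0.10, and without PLZF_ON replicate 2 they were 0.129 and 0.18. Without WT replicate 2 or PLZF_ON replicate 1 the median was 1.03 or 0.93.

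Interferon-stimulated transcripts had a median of -0.18 (27 measured, camera adjusted p = 0.0388, and adjusted p = 0.709 with an estimated correlation), and 0 passed limma adjusted over the list alone or over all rows, with 6 under an unadjusted p of 0.05. The camera call on this list was lost without WT replicate 1 (adjusted p = 0.0561), without WT replicate 2 (adjusted p = 0.0751) and among brighter rows alone (adjusted p = 0.0818), and without PLZF_ON replicate 2 the camera direction was the opposite (adjusted p = 0.868, median -0.02). Without PLZF_ON replicate 1 the interferon-stimulated median was -0.35. Glycolysis transcripts had a median of 0.20 (18 measured, camera adjusted p = 0.0472, and adjusted p = 0.569 with an estimated correlation). Adjusted over the list alone, 1 glycolysis gene rose, Ldhb (1.70-fold), and 0 passed over all rows. Without WT replicate 1 the camera adjusted p of glycolysis was 0.332 and the median 0.12, and without PLZF_ON replicate 2 they were 0.337 and 0.11. The glycolysis call was also lost with the replicate number as a block (camera adjusted p = 0.0623), brighter rows alone (0.0568), quantile normalization (0.0509), median centring (0.0501), the mean of a gene's rows (0.0707) and all 6 arrays (0.808), and was kept only without WT replicate 2 or PLZF_ON replicate 1.

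Sex-linked transcripts, listed as a check on the samples, had a median of 0.57 (4 measured, camera adjusted p = 0.013, and adjusted p = 0.445 with an estimated correlation). The Y-linked genes Eif2s3y and Uty rose 1.64-fold and 1.84-fold adjusted over the list alone, and 0 passed over all rows. Xist was between 10.70 and 11.13 on the 4 arrays, beside Y-linked transcripts on each of them. The labels do not give the sex of the animals, so a different mix of sexes between samples was not excluded as the source of this rise. Without PLZF_ON replicate 1 the camera adjusted p was 0.0508.

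The remaining lists did not pass camera over the 4 arrays. Without WT replicate 2 the TCR-induced and heat shock lists passed as higher (camera adjusted p = 0.00999 and 0.00782), and without PLZF_ON replicate 1 cytokines and chemokines passed as lower (0.0454). Of the TCR-induced and immediate early genes, 6 of 21 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.195), with Nr4a1 up 1.91-fold and Junb down 1.38-fold, and 0 passed over all rows. Of the inhibitory receptors and anergy genes, 5 of 17 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.178, and 0.00506 among brighter rows alone), with Cd200 up 3.34-fold, Btla up 1.86-fold and the ectonucleotidase Entpd1 down 2.29-fold. For cytokines and chemokines, 2 of 25 rose (Csf1 and Il13) and 2 fell (Ltb and Tnfsf10) adjusted over the list alone, with camera adjusted p = 0.723. In the apoptosis list 1 of 16 genes, the death promoter Bcl2l11, fell 1.71-fold adjusted over the list alone (camera adjusted p = 0.195). Regulatory and gamma-delta T cell markers had 1 rise (Gpr83) and 1 fall (Capg) among 7 adjusted over the list alone (camera adjusted p = 0.63). The T cell receptor gamma and delta genes of this list, such as Trdc and Trgv2, were not among the 7, so the list does not test for gamma-delta T cells by their receptor. Trgv5, a gamma variable segment outside this list, fell 4.92-fold, and whether gamma-delta T cells in the samples contributed was not tested. None of these 4 lists had a member that passed over all rows.

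Oxidative phosphorylation (29 measured) and heat shock (11) had 0 members passing limma adjusted over the list alone (1 and 0 under an unadjusted p of 0.05), with camera adjusted p = 0.43 and 0.391. Markers of B cells (19 measured), of macrophages, monocytes and dendritic cells (22), of neutrophils, mast cells and basophils (15), of erythroid cells and platelets (8) and of hepatocytes (13) also had 0 members passing limma, alone or over all rows, with at most 1 member of each under an unadjusted p of 0.05. Camera adjusted p-values of these 5 marker lists were 0.685, 0.86, 0.948, 0.714 and 0.654, and their median log2 differences lay between -0.05 and 0.03. In 3 lists the median, mean and camera direction differed in sign: cytokines and chemokines, the macrophage list and the regulatory and gamma-delta list.

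**Figure D2:**
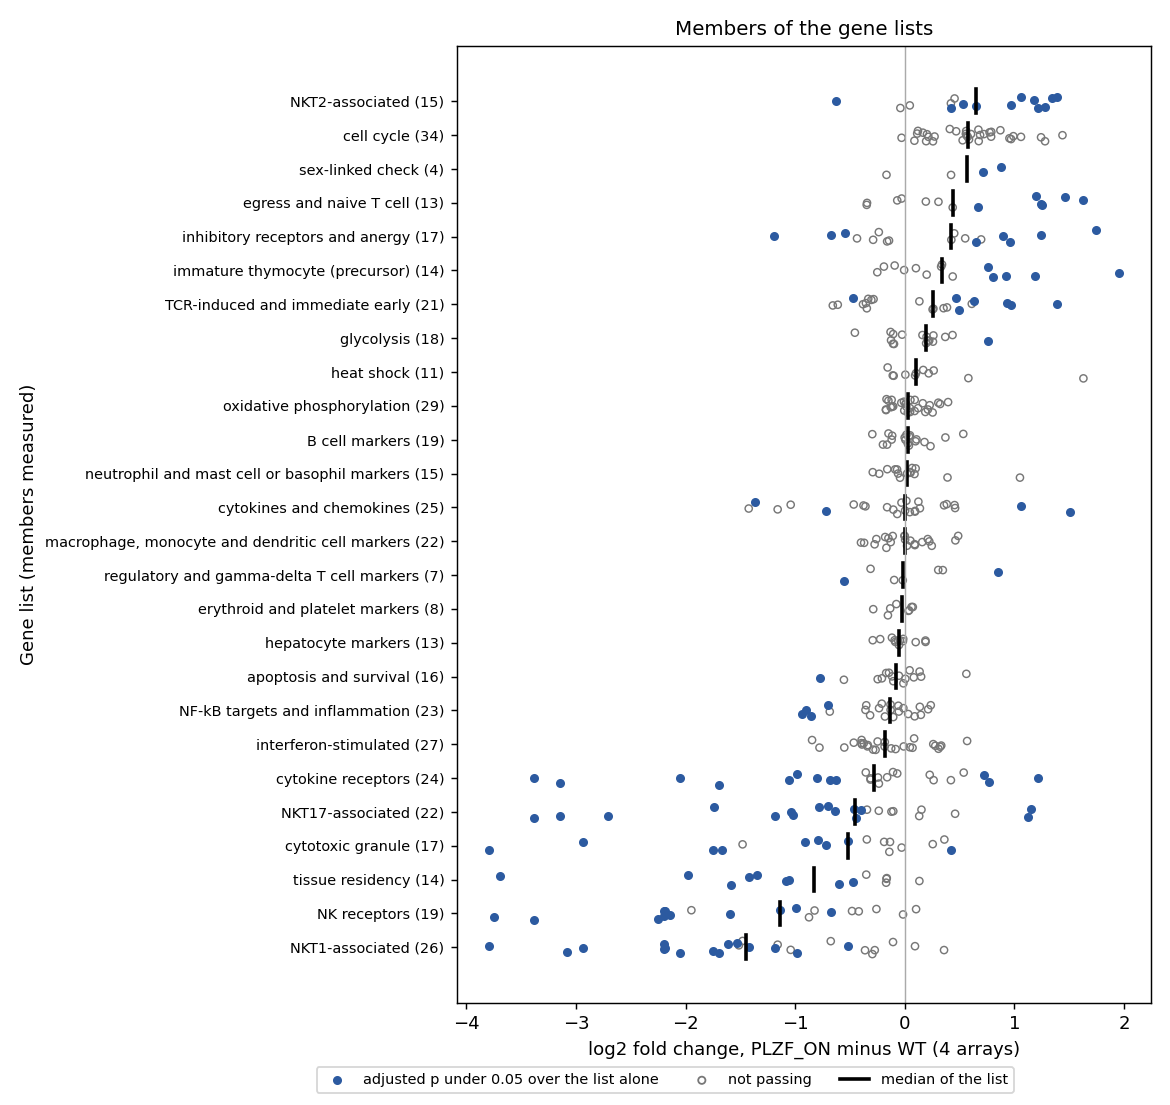
Log2 fold change of PLZF_ON minus WT over the 4 arrays (horizontal axis) for each measured member of the 26 gene lists (vertical axis, number measured in brackets), 1 point per gene, with a vertical bar at the list median. Filled points passed limma adjusted over the list alone; NKT1-associated genes lay lowest with a median of -1.45 and NKT2-associated genes highest with 0.65.

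The comparison over all 6 arrays asked whether these differences held with every labelled array. Itgae fell by 3.91 on the log2 scale, or 15.0-fold (SE 0.28, n = 3 arrays per group, limma adjusted p = 0.0116), Il23r fell 8.20-fold and Il1r1 7.93-fold. Akr1c18 rose 14.9-fold and Nrgn 7.25-fold (limma adjusted p = 0.0322 and 0.0425). Themis rose 3.64-fold, the p38-beta kinase Mapk11 2.69-fold and Tmlhe, an enzyme of carnitine synthesis, 2.62-fold. The kinase Styk1 and the interleukin-12 receptor chain Il12rb2 fell 4.99-fold and 4.94-fold. The lower group of Akr1c18, Il23r, Il1r1 and Mapk11 lay below the 95th percentile of the receptor genes over 6 arrays (5.21), against which their folds were 8.70, 3.03, 4.96 and 2.56. NKT1-associated transcripts were again lower, with 17 falls among 26 adjusted over the list alone. By limma none of these 10 genes passed without WT replicate 1 (adjusted p from 0.137), WT replicate 2 (from 0.0503) or PLZF_ON replicate 2 (from 0.0685), only Itgae passed without PLZF_ON replicate 1 (others from 0.0556), and only Il1r1 without WT replicate 3 (others from 0.0558).

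With 6 arrays, 22 rows passed a limma adjusted p of 0.05, 6 higher and 16 lower, standing for 21 genes. An unadjusted p under 0.05 was reached by 1358 rows, against 1176 expected by chance. Size and direction depended on scaling and weighting, with 5 rows (1 higher) under median centring, which kept 2 of the 10 named genes, and 259 rows (136 higher) under array weights. Of the 40 rows called over 4 arrays, 13 were also called over 6, in which the same 4 arrays take part. Of the 20 named genes 9 passed over 6 arrays, and those that did not included Moxd1, Vsig2, Irak3, Slc15a1, Slc12a2 and Spa17. The log2 differences of these 6 over all arrays lay between 1.36 and 3.09, and their limma adjusted p-values between 0.309 and 0.811. Without PLZF_ON replicate 3, 107 rows passed (64 higher and 43 lower), and these included all 22. The count was 0 with limma without WT replicate 1, WT replicate 2 or PLZF_ON replicate 2 in turn (852, 960 and 1531 rows under an unadjusted p of 0.05), 1 without WT replicate 3 and 6 without PLZF_ON replicate 1.

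Over 6 arrays 12 of 26 lists passed camera (4 higher and 8 lower), and 0 passed with an estimated correlation (smallest adjusted p = 0.0904, with 6 under an unadjusted p of 0.05). By fry 3 lists passed, NKT17-associated (adjusted p = 0.0355), tissue residency (0.0386) and immature thymocyte (0.039). NKT1-associated, NK receptor, cytotoxic granule and cytokine receptor transcripts had camera adjusted p-values of 4.6e-27, 1.7e-15, 2.1e-08 and 1.3e-07, and adjusted p = 0.16, 0.184, 0.184 and 0.331 with an estimated correlation. Tissue residency and NKT17-associated transcripts had camera adjusted p = 1.1e-17 and 2.1e-08, and adjusted p = 0.103 and 0.0904 with an estimated correlation. The immature thymocyte list had a median of 0.74 and camera adjusted p = 3.7e-08 (adjusted p = 0.0904 with an estimated correlation), and Cd24a and Dntt in PLZF_ON replicate 3 lay 4.85 and 3.30 above the mean of the other 5 arrays. Without PLZF_ON replicate 3 the median of this list was 0.40. Counts adjusted over the list alone were 11 falls for NK receptors, 8 for cytotoxic granule, 8 and 1 rise for cytokine receptors, 9 for residency, 9 and 1 rise for NKT17-associated transcripts, and 4 rises for the immature thymocyte list.

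NKT2-associated transcripts had a median of 0.52 over 6 arrays (camera adjusted p = 7.7e-04, and adjusted p = 0.525 with an estimated correlation), and 3 rose and 1 fell adjusted over the list alone. The call was lost without PLZF_ON replicate 1 (camera adjusted p = 0.0842) and without PLZF_ON replicate 2 (0.0949, median 0.31), and without PLZF_ON replicate 3 the median was 0.82. Egress and naive T cell transcripts had 5 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.00212, and adjusted p = 0.331 with an estimated correlation), and lost the camera call without PLZF_ON replicate 1 (0.0798). Cell cycle transcripts had a median of 0.44 (camera adjusted p = 3.1e-04, and adjusted p = 0.739 with an estimated correlation), and without PLZF_ON replicate 2 the camera direction was the opposite (adjusted p = 0.965, median 0.07). Without PLZF_ON replicate 3 the cell cycle median was 0.67. Interferon-stimulated and NF-kB lists had medians of -0.23 and -0.11 (camera adjusted p = 1.5e-04 and 3.2e-04, and adjusted p = 0.331 for both with an estimated correlation), the former lost without PLZF_ON replicate 3 (camera adjusted p = 0.0819, median -0.10).

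Glycolysis and sex-linked transcripts did not pass camera over 6 arrays (adjusted p = 0.808 and 0.369), but passed as higher without PLZF_ON replicate 3 (0.00204 and 0.0112). Oxidative phosphorylation (0.203) passed as lower without PLZF_ON replicate 1 (0.0135), PLZF_ON replicate 2 (0.0314) or WT replicate 3 (0.0348) and as higher without PLZF_ON replicate 3 (0.0393). The apoptosis list passed as lower without PLZF_ON replicate 1 (0.0457) or WT replicate 3 (0.0352), and the TCR-induced and heat shock lists without WT replicate 1 (0.0106 and 0.0267). B cell markers passed as higher without PLZF_ON replicate 2 (0.0413), and neutrophil markers without PLZF_ON replicate 1 (0.0172).

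The replicate 3 arrays, which took no part in the comparison over 4 arrays, were set against its results as a separate pair. The log2 difference of PLZF_ON minus WT was -4.35 for Itgae, -2.82 for Il23r and -2.44 for Fgl2, and Akr1c18 and Nrgn differed by 2.74 and 2.63. The lower array of Il23r (3.654) and of Akr1c18 (4.845) lay below the receptor percentile over 6 arrays (5.21), so the sizes of these 2 differences are uncertain. Spa17 and Slc15a1 had the opposite sign in this pair, with -0.35 and -0.07. With 1 array per group these values have no replicate check.

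Of the 40 called rows, 36 had the same sign in the replicate 3 pair, 20 of 24 among those higher and 16 of 16 among those lower in PLZF_ON. Among the 2213 rows with an unadjusted p under 0.05, 65.1% had the same sign (Wilson 95% interval 63.1% to 67.0%, which treats rows as independent although genes are not independent replicates). Of the 1148 higher rows 649 agreed (56.5%), against 57.6% of all rows higher over the 4 arrays, and of the 1065 lower rows 791 (74.3%), against 45.6% of all lower rows. Brighter rows leaned lower in this pair. Among rows at or above the median brightness 453 of 882 higher rows agreed (51.4%, against 39.4% of all such higher rows) and 683 of 809 lower rows (84.4%, against 67.8%). At an unadjusted p under 0.01 the shares were 63.2% of higher and 84.8% of lower rows. Over all 23521 rows the share was 51.5%, and the Pearson correlation of log2 differences across rows was 0.171. The list medians in this pair were -1.40 for NKT1-associated, -1.44 for NK receptor and -1.18 for tissue residency transcripts. NKT2-associated and cell cycle transcripts had medians of -0.16 and -0.03. Lists without a camera call over 4 arrays also moved in this pair. Medians were -0.46 for heat shock and -0.30 for oxidative phosphorylation, and between 0.19 and 0.32 for inhibitory receptors and the 5 marker lists of other cells.

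**Figure D3:**
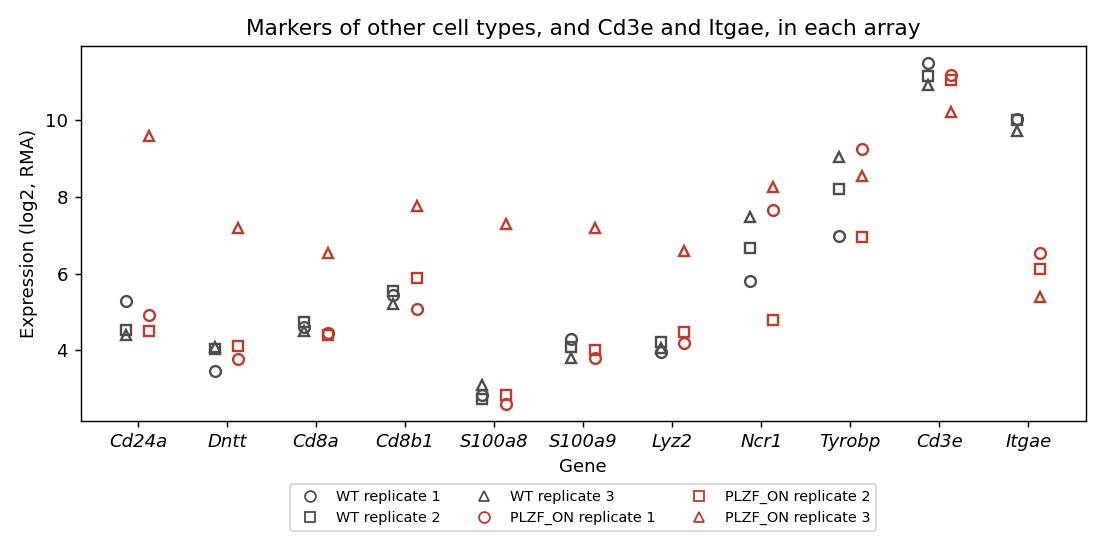
Expression in log2 units (vertical axis) on each of the 6 arrays for markers of immature thymocytes (Cd24a, Dntt, Cd8a, Cd8b1), neutrophils and myeloid cells (S100a8, S100a9, Lyz2) and natural killer cells (Ncr1, Tyrobp), and for Cd3e and Itgae (horizontal axis), 1 point per array. Cd24a was at 9.58 and S100a8 at 7.29 in PLZF_ON replicate 3, against means of 4.72 and 2.82 in the other 5 arrays.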

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

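For the 4-array count of 40, brighter rows alone, a variance trend, quantile normalization, median centring and array weights each gave a count within 1.5 times. The count was 101 with the replicate number as a block (65 higher), 22 with all 6 arrays, 135 at an adjusted p under 0.1, 972 at an unadjusted p under 0.05 with a 1.5-fold change, and 0 when all deposited rows were tested. In the test of all deposited rows the 17824 added rows varied more within groups (median SD 0.216 against 0.141 in the tested rows), and the prior degrees of freedom fell from 4.10 to 2.30; 1495 of the added rows had an unadjusted p under 0.05. Leaving out each array gave 0 to 106, with the lone array of a group assumed to vary like the other group. Among rows at or above the median brightness alone the count was 36 over 4 arrays and 28 over 6, and changes of dimmer rows are limited by signal over background.

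For the 6-array count of 22, the values were 5 with median centring, 259 with array weights, 46 at an adjusted p under 0.1, 802 at an unadjusted p under 0.05 with a 1.5-fold change and 0 with all deposited rows (limma, smallest adjusted p = 0.0808, with 2100 rows under an unadjusted p of 0.05). Leaving out each array gave 0 to 107, and the block gave 30. The cause was not tested. The replicate numbers were not taken as pairing because no protocol states one. Deviations of same-numbered arrays from their group means correlated at 0.092, 0.253 and 0.239 across rows over 6 arrays and at 0.132 over 4. Those of differently numbered arrays correlated between -0.235 and 0.124 over 6 arrays, and 5 of 6 arrays correlated best with their own number. These values do not speak against a pairing, which stays open. Under the block, the counts of lists passing camera went from 14 to 13, with glycolysis lost, and from 12 to 13, with neutrophil markers gained as higher (camera adjusted p = 0.0424), and 19 cell cycle genes passed adjusted over the list alone. Members passing over all rows went from 0 to 6 for NKT1-associated, 0 to 3 for cytotoxic granule, 1 to 3 for NK receptor, 1 to 3 for residency, 3 to 4 for NKT17-associated and 2 to 3 for cytokine receptor transcripts, and from 0 to 1 for cell cycle and inhibitory receptor lists.

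The glycolysis call over 4 arrays was also lost under quantile normalization, median centring, brighter rows alone and the mean of a gene's rows, and the interferon-stimulated call among brighter rows alone, where inhibitory receptors passed as higher (camera adjusted p = 0.00506 over 4 arrays and 0.0126 over 6). With an estimated correlation between genes the number of lists passing camera was 0 in both comparisons. The camera direction reversed for interferon-stimulated genes without PLZF_ON replicate 2 (4 arrays, 1 for higher), although their median kept its sign at -0.02. For cell cycle genes it reversed without PLZF_ON replicate 2 (6 arrays, -1 for lower, camera adjusted p = 0.965), and the median kept its sign at 0.07. For oxidative phosphorylation it reversed without PLZF_ON replicate 3 (6 arrays, 1 for higher, camera adjusted p = 0.0393). The cause of these changes was not tested. The same-sign share in the replicate 3 pair was 67.2% among brighter rows and 73.4% among rows with an unadjusted p under 0.01. The 20 genes named from 4 arrays and the 10 from 6 had the same direction under all alternatives in which they were measured. Most alternatives could not turn their sign, because these genes were chosen for groups that do not overlap. Only quantile normalization, median centring and, for the 20, the use of all 6 arrays could have done so. By scaling, quantile normalization and median centring left 20 and 20 of the 20 past the threshold, and 6 and 2 of the 10. Zbtb16 kept its direction under all its alternatives, from 0.24 to 0.62 in the 4-array comparison, and passed in none.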

Other observations

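Gene families were examined by symbol after the results were seen, and of the tests of explanations, those on paralogous probes, on thymocytes, neutrophils and other cell types in PLZF_ON replicate 3, on NK genes in PLZF_ON replicate 2 and on the chromosome of Zbtb16 were chosen after the result was seen. All 8 measured Gimap genes, which encode small GTPases of lymphocytes, were lower in PLZF_ON over the 4 arrays, with a median of -0.52 (camera adjusted p = 6.5e-05 over the 20 families tried, and adjusted p = 0.739 with an estimated correlation). Their median was -0.45 over all 6 arrays (camera adjusted p = 6.0e-05, and adjusted p = 0.773 with an estimated correlation) and negative under quantile normalization and median centring. No Gimap gene passed limma alone. Small nucleolar RNAs (74 measured) had a median of -0.21 (camera adjusted p = 0.0043, and adjusted p = 0.739 with an estimated correlation), with camera adjusted p = 0.115 over all 6 arrays. Chemokine receptors went both ways, and as a family did not pass (camera adjusted p = 0.929). Ccr8 had a log2 difference of -2.08, Cxcr3 -1.61 and Cxcr6 -1.08, against 1.25 for Ccr7, 1.19 for Ccr9, 1.18 for Ccr4 and 0.77 for Cxcr4 (limma adjusted p from 0.0986 to 0.264). Of the TNF ligands Tnfsf8 passed, and Tnfsf4, which encodes OX40 ligand, had a log2 difference of 1.62 (limma adjusted p = 0.171).

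Syne1, which encodes a large nuclear envelope protein, has 59 rows on the array, and all 59 were higher in PLZF_ON over the 4 arrays. Of these, 48 were higher by over 1 on the log2 scale and 1 passed limma. The row that passed had the opposite sign in the replicate 3 pair (-3.18). Over all 6 arrays its log2 difference was 0.17 (limma adjusted p = 0.984). The median over these rows was 5.64, 6.39 and 6.14 in WT replicates 1 to 3 and 7.41, 7.80 and 6.23 in PLZF_ON replicates 1 to 3. P2rx7, an ATP-gated channel, had a log2 difference of 2.24 (limma adjusted p = 0.102 over 4 arrays and 0.0456 without PLZF_ON replicate 3). Ikzf3, the lymphoid transcription factor Aiolos, had -1.97 (limma adjusted p = 0.075 over 4 arrays) and passed over 6 with -2.09 (adjusted p = 0.0454). The heat shock gene Hspa1a was at 4.17 in WT replicate 1 against 8.27 and 9.81 in WT replicates 2 and 3 and between 7.60 and 7.94 in PLZF_ON. Xist was at 9.31 or above and Eif2s3y at 6.76 or above on all 6 arrays.

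The lower NKT1-associated and NK receptor transcripts in PLZF_ON were set against a larger share of NK cells in the WT samples, most of which a sort for iNKT cells, if done, would remove. The 6 measured NK genes, 2 of them NK receptors of that list, went both ways, with Clnk at -1.63 and a median of 0.0908 (interquartile range 0.65) against -1.45 for the NKT1-associated list, which argues against NK cells as the whole cause. Their median lay 1.23 above the WT mean in PLZF_ON replicate 1 but was -1.09 in replicate 2, and the difference of -2.21 between the 2 exceeded that of the NKT1-associated list (-1.17), so fewer NK cells may be part of the fall in replicate 2. Probes shared among Klr paralogs could not account for the NKT1-associated list, since 21 of its 23 genes outside that family were lower, with a median of -1.18, but for NK receptors they stay open. A smaller share of NKT1 cells or lower expression per cell in PLZF_ON both stay open, as untested hypotheses.

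PLZF_ON replicate 3 stood apart from the other arrays. A compressed range of values may account for part of this, since olfactory and vomeronasal receptor genes had a median 0.39 above the other 5 arrays and the 2218 brightest genes a median of -0.58. RNA of immature thymocytes may also be present, since 35.7% of 14 immature thymocyte genes lay over 1 log2 unit above the other arrays (Wilson 95% interval 16.3% to 61.2%), against 9.25% of the receptors (7.84% to 10.9%), with Cd24a at 9.58, Cd8b1 at 7.77 and Dntt at 7.19; of the 5 genes over that limit 4 were below the median gene in the other arrays, where compression also raises values, and 1 of the 14 is in another list. Neutrophil RNA is a further candidate, with 26.7% of 15 neutrophil, mast cell and basophil genes over that limit (10.9% to 52.0%), S100a8 at 7.29 and S100a9 at 7.20; all 4 genes over the limit were below the median gene elsewhere, and none of the 15 is in another list. The 77 markers of other cell types pooled, neutrophils included, did not exceed the receptors (7.79%, with a lower interval bound of 3.62%), which leaves other cells open, and a sort for iNKT cells, if done, would remove most such cells.

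Called genes were examined around Zbtb16, since DNA of another strain kept beside an altered gene could change its neighbours. Of 200 measured genes on either side 9.5% had an unadjusted p under 0.05, against 9.19% of all genes. This put the window at percentile 62.1 of all windows, which argues against a change across that window as a whole. A share over so many genes could not show a change in a few of them. Inside the window lies 1 called gene, Exph5, and just outside it the called genes Vsig2, Nrgn and Spa17 lie side by side. All 4 were higher in PLZF_ON. Among the 39 called genes 3 pairs were adjacent in gene order, a count not set in advance. They were Vsig2 with Nrgn, Nrgn with Spa17, and Itgae with Haspin, which overlap. In 10000 random draws of as many genes, taken from all placed genes at any level, 0 gave as many pairs (mean 0.0699). The highest count in a draw was 2, as many as the run of Vsig2, Nrgn and Spa17 gives without the overlapping pair. Of the 39 called genes 5 lie on the chromosome of Zbtb16, against 2.22 expected (Fisher's exact test, two-sided, p = 0.0693), so linked DNA stays open for single genes there, Exph5 included.

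Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave 22 called rows, and the highest of the others gave 0. With 10 splits the share cannot be under 0.05.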
